A study of Mus musculus with 14 samples.

How the data were processed

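RNA sequencing libraries were made from mouse bone marrow-derived macrophages of 2 genotypes in 2 media, 14 libraries in 4 groups. Per the labels' protocols, marrow cells were cultured for 7 to 10 days with 10% fetal bovine serum, 5% horse serum and 20% L929 cell medium, and treated for 24 h. Per the labels' protocols, RNA was sequenced as paired reads of 150 bp. Raw counts were deposited by the authors, after alignment with HISAT2 to mm10 per the submitters' processing notes, which give no version, counting tool, annotation or strand setting in the sources used here. The groups and replicate numbers come from the samples' labels, and the file's columns were matched to samples by the names in the samples' descriptions.

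The deposited table holds 427386 exon entries of transcript models over 25239 gene symbols, and 0 entries name no gene. An exon shared by several transcript models is listed once for each, with the same length and counts. Of the entries, 196941 repeat another entry of the same gene and hold 48.6% of the count total. They were removed, which left 230445 distinct exons, and gene counts are the sums of those. A fragment that spans several exons can be counted in each, so gene counts are not numbers of fragments. The most-counted exon of each gene holds 27.3% of the total. Of all symbols, 18364 had a count. The mitochondrial transcripts are not in the table.

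Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM factors, filterByExpr with a minimum count of 10 and minimum total of 15). One fit with a mean for each of the 4 groups over all 14 libraries gave 5 comparisons: CM in WT, CM in KO, KO in control medium, KO in CM and the interaction. P-values were adjusted by the Benjamini-Hochberg method over all tested genes within a comparison, and a gene was called at an adjusted p below 0.05. Gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes, adjusted over the 33 lists with 5 or more tested members in each comparison. Of 43 lists fixed beforehand, those with fewer tested members were not tested. Beside each list stand its median, the numbers of called members, and the numbers called when p-values are adjusted over the list alone. Camera with an estimated correlation and fry were run as alternatives.

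The genes named were set by a rule fixed before the files were seen. It names Ezh2, and the 6 largest increases and 6 largest decreases among called genes with a mean of 4 CPM or more whose groups do not overlap, leaving out predicted, clone, immunoglobulin and T cell receptor symbols. It also names up to 4 members of each list with the smallest p, 14 genes of macrophage activation, and for the interaction the 3 smallest p in each direction. Members of a list were chosen for the text from these 4, preferring calls that no left-out library ended. For genes with 3 counts or fewer in a group, ratios carry a 95% counting interval, and for genes with 0 counts a bound against 3 counts.

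Exon shares of each gene, the ratio of 3' to 5' coverage over 431 genes, the ratio of 2 Ezh2 exons to the others, and fits within the groups of libraries that the exon shares showed were added after the data were seen.

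The fit was tested on simulated counts with 200 changed genes. Of the genes changed 2-fold, it recovered 94% for CM in WT, 98.5% for CM in KO, 89.6% for KO in control medium, 88.1% for KO in CM and 82.1% for the interaction, over 13202 genes in the first. At 1.5-fold these were 80.6, 67.2, 83.6, 74.6 and 40.3%. The changed genes had a mean of 1 CPM or more, and the simulated libraries were independent and without batches. The rates therefore do not describe weakly expressed genes or libraries that differ by batch. Whether replicate numbers pair libraries was checked by correlating deviations from the group means. In WT, control and CM libraries of the same number correlated with 0.33, 0.35, 0.47 and 0.46, all above the limit of 0.1 set beforehand, so by that rule the numbers pair the WT libraries. Libraries of one batch also correlated across numbers, up to 0.31 and 0.35 for control libraries 1 and 2 and 0.46 and 0.37 for 3 and 4. The batch may thus account for nearly all of the pairing.

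Alternatives set beforehand were DESeq2 size factors, library totals alone, 2 other filters, DESeq2 1.42.0, limma-voom with quality weights, a fit of only the compared groups, the replicate number as a block, other thresholds, and leaving out each library in turn. Alternatives added after the data were seen were all exon entries, the most-counted exon of each gene, the library batch as a term, and WT libraries 1 and 2 or 3 and 4 alone.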

Results

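RNA was sequenced from 14 cultures of mouse bone marrow-derived macrophages (BMDMs), macrophages grown from marrow precursors. Cells came from mice in which the Cre recombinase under the lysozyme M promoter deletes floxed Ezh2 in myeloid cells (KO) and from littermates that keep Ezh2 (WT). Each genotype was cultured for 24 h in control medium (DMEM by the column names) or in medium conditioned by Hepa1-6 cells, a mouse hepatoma line (CM). No medium conditioned by other cells was included, so a response to CM cannot be credited to tumor cells in particular. There were 4 WT libraries in each medium and 3 KO libraries in each medium. Exon counts summed to 45.2 to 82.1 mega-counts (M) per library for WT in control medium, 41.3 to 85.8 M for WT in CM, 41.8 to 54.4 M for KO in control medium and 40.2 to 61.5 M for KO in CM. The labels do not say whether libraries of one group came from separate animals, so p-values measure the spread between these samples, which may be technical. The test, the comparisons, the gene lists and the rule for naming genes were set before the data were examined. Changes are log2 fold changes ± SE where no other unit is named. Levels are counts per M of the TMM-scaled library total (CPM) ± SD. The SE is approximate, and for genes almost without counts in a group it does not measure the precision of the fold. Arg1 had an SE of 0.32 for CM in WT and 0.34 for CM in KO. For the difference of these responses, the interaction, its SE was 1.54.

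The medium separated the libraries on the first principal component of log CPM, which held 55.5% of the variance. The second component (14.9%) set WT libraries 3 and 4 of both media apart from the other 10. These 4 libraries also differed in how counts were spread over the exons of each gene: on the first component of exon shares (52.1% of variance over 97428 exons) they lay at 0.398 to 0.445 and the other 10 at -0.148 to -0.208. They were the deepest libraries, at 80.4 to 85.8 M counts against 40.2 to 61.5 M. Their median log2 ratio of 3' to 5' coverage was -0.077 to -0.108, against -0.237 to -0.361 in WT libraries 1 and 2 and -0.248 to -0.364 in KO. RNA or library quality may therefore also differ between WT libraries 3 and 4 and the KO. The labels name no batch, so the batch is inferred from these values. WT libraries 1 and 2 grouped with all KO libraries in exon shares and coverage, so KO was compared with them alone, called within the batch below. On the third component (5.5%) they lay apart from KO (-25.6 to -11.5 against 4.9 to 13.9), so a further technical difference is not excluded. KO against WT libraries 3 and 4 cannot be told apart from that batch.

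The knockout was visible in 2 exons of Ezh2, which encodes the catalytic subunit of the H3K27 methyltransferase complex PRC2. Ezh2 lies on chromosome 6 from 47530274 to 47595270 (mm10). Exon 18 (chromosome 6, 47531985 to 47532065, 81 bp) and exon 19 (chromosome 6, 47531741 to 47531825, 85 bp) were chosen after their values were seen, so no p-value is given for them. Their count per base, as a percentage of that over exons 2 to 17, was 14.2 ± 13.2% (SD, n = 3) in KO and 116.6 ± 26.8% (n = 4) in WT in control medium, and 12 ± 5.3% (n = 3) against 99.7 ± 17.7% (n = 4) in CM. In neither medium did the KO and WT libraries overlap. Counts remained in these exons in KO libraries, from 1.8% (KO control library 3) to 28.0% (KO control library 2), so the deletion need not be complete. Neither EZH2 protein nor H3K27 methylation was measured in these data. The summed Ezh2 level moved less, since the other exons were still counted: 22.98 ± 2.89 CPM in WT and 18.58 ± 0.29 CPM in KO in control medium (-0.31 ± 0.10, edgeR adjusted p = 0.0761), and 35.66 ± 3.27 against 27.13 ± 2.22 CPM in CM (-0.40 ± 0.10, edgeR adjusted p = 0.0334). Against WT libraries 1 and 2 alone, the Ezh2 differences were -0.15 (edgeR adjusted p = 0.439) and -0.34 (edgeR adjusted p = 0.0536). The Ezh2 call in CM was lost without WT CM library 2, 3 or 4 (adjusted p = 0.056, 0.0684 and 0.0985), KO control library 1 (0.051) or KO CM library 1, 2 or 3 (0.0855, 0.122 and 0.076). In control medium Ezh2 passed without WT control library 1 (-0.37, 0.039) or 2 (-0.34, 0.0473). CM raised the summed Ezh2 level in WT (0.63 ± 0.09, edgeR adjusted p = 3.99e-05) and in KO (0.55 ± 0.11, edgeR adjusted p = 0.000686).

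**Figure D1:**
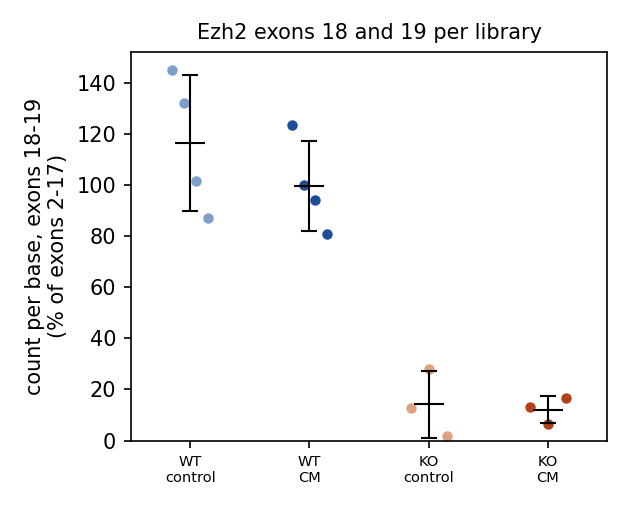
Count per base over Ezh2 exons 18 and 19 as a percentage of that over exons 2 to 17 (y axis), by group (x axis). Points are libraries, the horizontal marks are group means and the bars are SD. The 6 KO libraries lie between 1.8 and 28.0%, below the 8 WT libraries at 81.1 to 145.2%.

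The first comparison asks what hepatoma-conditioned medium does to WT macrophages. CM turned on Arg1, the arginase of alternatively activated (M2) macrophages, from 0.0362 ± 0.0464 CPM to 68.2 ± 9.48 CPM (SD, n = 4 each, 10.49 ± 0.32). Arg1 was at 0 CPM in WT control libraries 1 and 2, and the fitted change within WT libraries 1 and 2 was 14.65. The size of the fold is therefore uncertain, by more than its SE of 0.32 states. Genes of cholesterol synthesis, mitosis, glycolysis, the unfolded protein response and hypoxia rose. Monocyte chemokines rose with them. Growth factor response genes (10 of 19 higher, 5 lower) and MHC class II genes (9 of 14 lower, 1 higher) also passed camera, but each had adjusted p = 0.05003 with an estimated correlation. Of 13311 genes tested, 4960 passed edgeR's quasi-likelihood test at an adjusted p of 0.05, 2570 higher and 2390 lower. At 2-fold or more there were 584 higher and 419 lower.

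Among genes admitted by the naming rule (mean of 4 CPM or more, groups not overlapping, no clone symbols), the largest increases after Arg1 included those in Selp (P-selectin; 9.33 ± 0.22), Cd38 (an enzyme that degrades NAD; 8.21 ± 0.24), F5 (coagulation factor V; 6.23 ± 0.19) and Rasgrp1 (a Ras activator; 5.98 ± 0.21). The largest decreases under that rule were in Angptl4, an inhibitor of lipoprotein lipase (-4.16 ± 0.20), the fractalkine receptor gene Cx3cr1 (-3.88 ± 0.15), Spata13 (-3.57 ± 0.18), the immediate early gene Fos (-3.08 ± 0.14), Hpgd, which inactivates prostaglandins (-3.02 ± 0.16), and the corepressor gene Tle1 (-2.94 ± 0.09). Their edgeR adjusted p-values lay between 1.98e-13 (Selp) and 5.03e-10 (Hpgd).

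Among 29 measured genes of the alternative activation list, 15 rose and 3 fell (16 and 3 adjusted over the list alone, median 0.43, camera adjusted p = 5.19e-11). Clec10a, a lectin (2.11 ± 0.05), the IL-4 receptor gene Il4ra (1.89 ± 0.05) and Klf4 (2.20 ± 0.10) rose beside Arg1. Mrc1, the mannose receptor CD206, rose from 403.8 ± 59.4 to 846.4 ± 79.7 CPM (1.07 ± 0.09, edgeR adjusted p = 1.91e-07). Retnla had 0 counts in WT control medium and 391 in CM, at least 140-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 8.19e-06). Such bounds, and the counting intervals given for very low counts, cover at most counting error. They treat each count as a separate fragment, while a fragment can be counted in several exons, so they may be too narrow. Cd163 rose by 0.22 ± 0.07 (edgeR adjusted p = 0.0236), a call lost without WT control library 3 or 4 or WT CM library 2 or 4 (adjusted p = 0.0715, 0.0679, 0.0839 and 0.0517). Chil3 (-0.15 ± 0.38, edgeR adjusted p = 0.806) and Il10 (-0.40 ± 0.18, edgeR adjusted p = 0.0965) did not pass. Il10 did without WT CM library 3 (-0.53, adjusted p = 0.0452), with the library batch as a term (-0.42, 0.0316) and within WT libraries 1 and 2 (-0.71, 0.0337).

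The classical activation (M1) list went both ways, 6 of 23 members higher and 5 lower (7 and 5 adjusted over the list alone, median 0.10, camera adjusted p = 0.0921). It passed with the replicate number as a block (camera adjusted p = 0.0313) and without WT CM library 1 (0.0457). Cd38 and Socs3 (2.95 ± 0.17) rose while Cxcl10 (-1.67 ± 0.20) and Tnf (-1.23 ± 0.15, edgeR adjusted p = 1.05e-05) fell. Il6 rose from a very low level (3.71 ± 0.94, edgeR adjusted p = 0.00532), which did not pass within WT libraries 1 and 2 (adjusted p = 0.075). Il1b changed by 0.22 ± 0.34 (edgeR adjusted p = 0.667), and Nos2 and Il12b had too few counts in all 14 libraries to be tested (76 and 34). In the list of checkpoint and suppressive molecules, 12 of 22 rose and 6 fell (13 and 9 adjusted over the list alone, median 0.33, camera adjusted p = 0.0145). Cd274, encoding the checkpoint ligand PD-L1, rose from 38.9 ± 2.20 to 72.2 ± 0.84 CPM (0.89 ± 0.05, edgeR adjusted p = 2.21e-09), Arg2 rose by 2.12 ± 0.14, and Havcr2 fell by 1.33 on the log2 scale. Vegfa, the angiogenic growth factor gene, rose by 0.60 ± 0.07 (edgeR adjusted p = 7.92e-06), and Lyz2 did not pass (-0.10 ± 0.06, edgeR adjusted p = 0.262). Lyz2 passed without WT control library 4 (-0.16, adjusted p = 0.0478) and within WT libraries 1 and 2 (-0.25, 0.000316), but was 0.07 within WT libraries 3 and 4.

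All 24 measured cholesterol synthesis genes rose (24 adjusted over the list alone, median 1.39, camera adjusted p = 1.95e-42). They include Insig1 (2.00 ± 0.05) and Idi1 (2.04 ± 0.07). In glycolysis 20 of 23 rose and 1 fell (the same numbers over the list alone, median 0.65, camera adjusted p = 4.03e-10). Pfkl rose by 1.41 ± 0.07 and Ldha by 0.98 ± 0.05. Hypoxia response genes rose in 14 of 23 cases and fell in 3 (15 and 3 adjusted over the list alone, median 0.47, camera adjusted p = 1.76e-05). Bhlhe40 rose by 2.60 ± 0.06 and Pdk1 by 0.57 ± 0.05. Of 25 unfolded protein response genes, 22 rose and 1 fell (23 and 1 over the list alone, median 0.60, camera adjusted p = 5.83e-10). Pdia6 rose by 0.84 ± 0.04 and Hsp90b1 by 0.75 ± 0.05. The ATF4 and amino acid list had 13 of 31 higher and 3 lower (the same over the list alone, median 0.17, camera adjusted p = 0.00721). Wars changed by 1.44 ± 0.06 and Atf3 by -1.14 ± 0.06. Nuclear genes of oxidative phosphorylation rose in 23 of 41 cases with 0 lower (median 0.23, camera adjusted p = 0.00354), but adjusted p = 0.412 with an estimated correlation.

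Mitosis genes rose in 33 of 36 cases with 0 lower (34 adjusted over the list alone, median 1.41, camera adjusted p = 2.41e-32). They include Hmmr (2.05 ± 0.10), Mki67 (1.66 ± 0.08) and Kif2c (2.23 ± 0.12). Of 18 monocyte chemokines and receptors, 12 rose and 4 fell (the same over the list alone, median 1.57, camera adjusted p = 1.1e-10). Ccl6 (4.23 ± 0.12), Ccr1 (3.96 ± 0.13) and Ccl2 (3.5 ± 0.13) rose. Growth factor response and survival genes had 10 of 19 higher and 5 lower (the same over the list alone, median 0.18, camera adjusted p = 0.000246, adjusted p = 0.05003 with an estimated correlation, just above the threshold). Socs2 (5.64 ± 0.21), Cish (3.81 ± 0.17) and Pim1 (1.98 ± 0.09), induced by cytokine receptors, rose most surely in that list. In MHC class II presentation 9 of 14 fell and 1 rose (the same over the list alone, median -0.41, camera adjusted p = 1.76e-05, adjusted p = 0.05003 with an estimated correlation, just above the threshold). H2-Ab1 changed by -1.53 ± 0.08 and Cd74 by -1.10 ± 0.07. Interferon response genes fell in 30 of 44 cases and rose in 3 (30 and 4 over the list alone, median -0.53, camera adjusted p = 2.65e-05), but adjusted p = 0.469 with an estimated correlation. Ifit3 changed by -1.87 ± 0.20.

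Markers of other myeloid cells moved as well. Of 14 monocyte markers 6 rose and 3 fell (6 and 4 over the list alone, median 0.39, camera adjusted p = 0.00812, adjusted p = 0.142 with an estimated correlation). Vcan changed by 2.76 ± 0.11, Fn1 by 4.69 ± 0.19 and Nr4a1 by -3.33 ± 0.17. Of 10 neutrophil and granulocyte precursor markers 5 rose and 1 fell (the same over the list alone, median 0.15, camera adjusted p = 0.0215, adjusted p = 0.113 with an estimated correlation and 0.0536 with the replicate block). Mmp8 rose by 1.74 ± 0.08, Prtn3 rose by a count ratio of 294 (95% counting interval 100 to 1430, from 3 counts in control medium), and Elane by a ratio of 15.8 (5.07 to 79.6, also from 3 counts). Elane did not pass within WT libraries 1 and 2 (adjusted p = 0.12). Lysosome genes rose in 18 of 35 cases and fell in 8 (20 and 9 over the list alone, median 0.17, camera adjusted p = 0.000148, adjusted p = 0.0732 with an estimated correlation). Ctsc rose by 1.18 ± 0.04 and Ctsd by 0.91 ± 0.04. Immediate early genes fell in 13 of 28 cases and rose in 5 (14 and 5 over the list alone, median -0.28, camera adjusted p = 0.0216, adjusted p = 0.536 with an estimated correlation), and that list did not pass without WT control library 3 or 4 (0.0623 and 0.0527). The core macrophage list did not pass (6 of 24 higher, 8 lower, the same over the list alone, median -0.05, mean 0.03, camera direction up, adjusted p = 0.921). Itgam changed by 1.30 ± 0.04 and Adgre1, which encodes F4/80, by -0.69 ± 0.05. The NF-kB and TNF list did not pass either (9 of 30 higher, 12 lower; 10 and 13 over the list alone, median -0.08, mean 0.20, camera direction up, adjusted p = 0.49), with Sod2 at 1.13 ± 0.05.

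The CM response was present in both batches of WT libraries: 4348 genes passed with libraries 1 and 2 alone and 4889 with libraries 3 and 4 alone. The share of higher against lower genes depended on the scaling, with 1957 higher and 3501 lower when libraries were scaled by their totals alone.

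**Figure D2:**
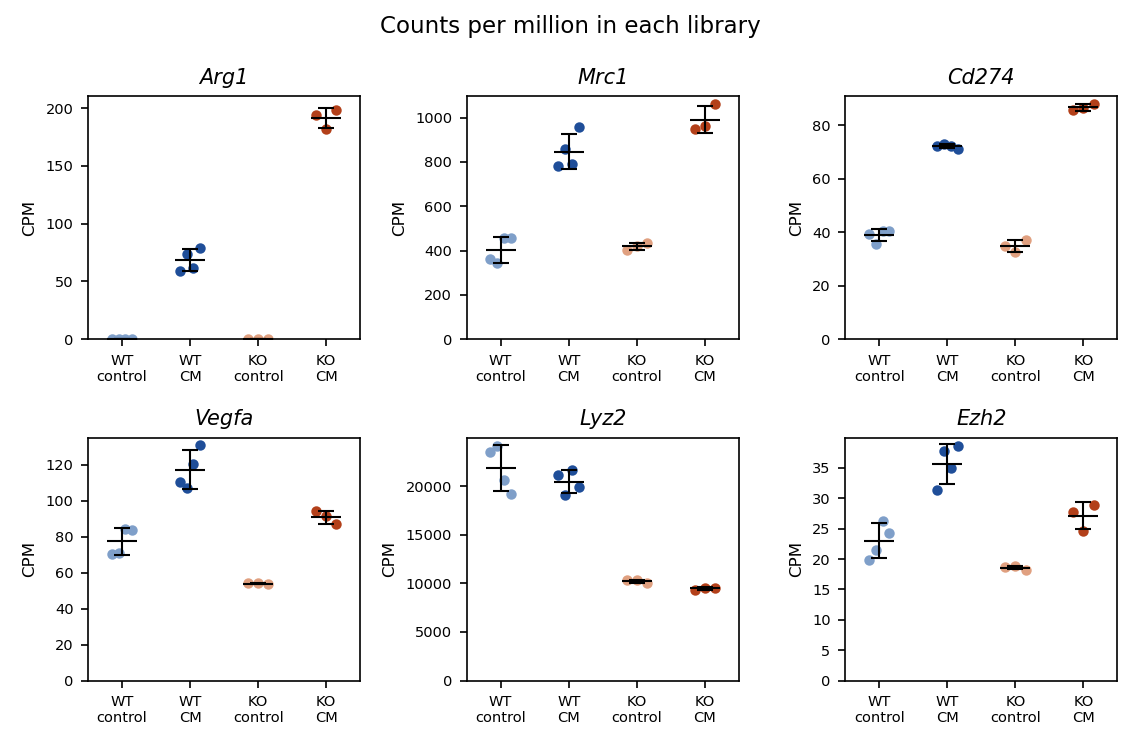
CPM (y axis, linear, from 0) of Arg1, Mrc1, Cd274, Vegfa, Lyz2 and Ezh2 in each library, by group (x axis). Points are libraries, the horizontal marks are group means and the bars are SD; Arg1 in CM lies at 68.2 ± 9.48 CPM in WT and 191.3 ± 8.75 CPM in KO.

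The same question was asked of KO macrophages. In KO cells CM again switched on Arg1 (10.60 ± 0.34), raised cholesterol synthesis, mitosis, glycolysis and unfolded protein response genes, and lowered MHC class II genes. In all, 5077 of 13311 genes passed edgeR's test, 2659 higher and 2418 lower; 662 were higher and 525 lower by 2-fold or more. Of the genes called in WT, 2087 were also called higher and 1798 also called lower in KO, where 513 and 434 would be shared by independent lists (odds ratios 76.7 and 50.4). Across genes, which are not independent replicates, the 2 responses correlated with r = 0.882 (Pearson) and 0.795 (Spearman), and r was 0.800 with WT libraries 1 and 2 alone and 0.834 with WT libraries 3 and 4 alone.

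Among genes admitted by the naming rule (mean of 4 CPM or more), the largest increases in KO included those in Selp, with 1 count in control medium and 9398 in CM (ratio 10000, counting interval 1800 to 395000), Cd38 (10.65 ± 0.34), Arg1, Rasgrp1 (7.37 ± 0.28) and the growth factor gene Nrg1 (7.07 ± 0.53). Angptl4 (-4.29 ± 0.22), Spata13 (-4.18 ± 0.22), Cx3cr1 (-4.04 ± 0.17), the receptor gene Gpr34 (-3.41 ± 0.16), Fos (-3.32 ± 0.17) and Hpgd (-3.19 ± 0.18) fell most among genes admitted by it. Their edgeR adjusted p-values were 3.79e-08 (Nrg1) or smaller.

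In the alternative activation list 17 of 29 rose and 3 fell (18 and 4 adjusted over the list alone, median 0.63, camera adjusted p = 5.91e-11), with Clec10a at 2.54 ± 0.06, Il4ra at 1.95 ± 0.06 and Klf4 at 2.44 ± 0.11. Mrc1 rose from 420.1 ± 15.5 to 989.8 ± 60.3 CPM (SD, n = 3 each; 1.24 ± 0.11, edgeR adjusted p = 2.23e-07), and Retnla by a count ratio of 126 (42.9 to 616, from 3 counts). Cd274 rose from 34.9 ± 2.20 to 86.7 ± 1.21 CPM (1.31 ± 0.06, edgeR adjusted p = 2.2e-10) and Vegfa by 0.75 ± 0.09, while Tnf fell by 1.19 on the log2 scale (edgeR adjusted p = 0.000101). Cd163 (0.19 ± 0.08, edgeR adjusted p = 0.0764), Il10 (-0.09 ± 0.22), Il1b (-0.74 ± 0.43), Il6 (2.23 ± 1.07), Chil3 (-0.69 ± 0.46) and Lyz2 (-0.11 ± 0.07) did not pass. Without KO CM library 1, Cd163 passed (0.27, adjusted p = 0.0246). Il1b passed without WT CM library 4 (-0.75, adjusted p = 0.0487) or KO CM library 3 (-1.32, 0.0407). Il6 passed without KO control library 1 (fitted 6.67, adjusted p = 0.0233). The remaining KO control libraries had 0 Il6 counts, so the size of that fold is not defined. In the fit with WT libraries 1 and 2 alone Cd163 (0.20, 0.0357), Il1b (-0.74, 0.0365) and Lyz2 (-0.11, 0.0221) passed. Checkpoint molecules had 13 of 22 higher and 7 lower (the same over the list alone, median 0.30, camera adjusted p = 0.00541), and the M1 list 5 of 23 higher and 7 lower (the same over the list alone, median 0.10, camera adjusted p = 0.229).

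Cholesterol synthesis genes rose in 23 of 24 cases (24 adjusted over the list alone, median 1.66, camera adjusted p = 2.55e-48), including Insig1 (2.23 ± 0.06) and Idi1 (2.37 ± 0.09). Mitosis genes rose in 35 of 36 (36 over the list alone, median 1.59, camera adjusted p = 1.56e-31), with Top2a at 1.76 ± 0.11. Glycolysis had 20 of 23 higher and 1 lower (the same over the list alone, median 0.73, camera adjusted p = 1.79e-10), with Pfkl at 1.42 ± 0.08. The unfolded protein response had 21 of 25 higher and 1 lower (22 and 1 over the list alone, median 0.64, camera adjusted p = 9.5e-10), with Pdia4 at 1.05 ± 0.06. Hypoxia genes had 14 of 23 higher and 3 lower (the same over the list alone, median 0.53, camera adjusted p = 6.2e-06), with Bhlhe40 at 2.96 ± 0.08. Of the chemokines and receptors 12 of 18 rose and 4 fell (the same over the list alone, median 1.52, camera adjusted p = 9.5e-10). Ccl2 rose by 4.27 ± 0.16. MHC class II genes fell in 10 of 14 cases and rose in 1 (the same over the list alone, median -0.86, camera adjusted p = 2.33e-08). H2-Ab1 changed by -2.13 ± 0.09 and H2-Eb1 by -2.10 ± 0.11. Growth factor response genes had 10 of 19 higher and 5 lower (10 and 6 over the list alone, median 0.18, camera adjusted p = 0.000707, adjusted p = 0.0802 with an estimated correlation), with Socs2 at 6.14 ± 0.26. Interferon response genes fell in 31 of 44 cases and rose in 3 (31 and 4 over the list alone, median -0.58, camera adjusted p = 8.55e-05), but adjusted p = 0.536 with an estimated correlation.

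Further lists passed in KO. The ATF4 and amino acid list had 15 of 31 higher and 3 lower (the same over the list alone, median 0.40, camera adjusted p = 0.000945), and lysosome genes 18 of 35 higher and 9 lower (21 and 9 over the list alone, median 0.18, camera adjusted p = 0.000198, adjusted p = 0.0803 with an estimated correlation). Monocyte markers had 6 of 14 higher and 3 lower (the same over the list alone, median 0.62, camera adjusted p = 0.0125, adjusted p = 0.187 with an estimated correlation). Angiogenic and matrix-remodelling factors had 15 of 30 higher and 10 lower (the same over the list alone, median 0.80, camera adjusted p = 0.0355, adjusted p = 0.29 with an estimated correlation), and lipid-associated macrophage genes 10 of 24 higher and 6 lower (10 and 7 over the list alone, median 0.03, camera adjusted p = 0.0144, adjusted p = 0.138 with an estimated correlation). In WT these last 2 lists did not pass (camera adjusted p = 0.0898 and 0.0994).

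Scaling by library totals alone gave 1941 higher and 3624 lower genes for CM in KO. It moved the median of all genes by -0.107 (log2) in this comparison, and all changes given here are relative to the TMM scaling.

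**Figure D3:**
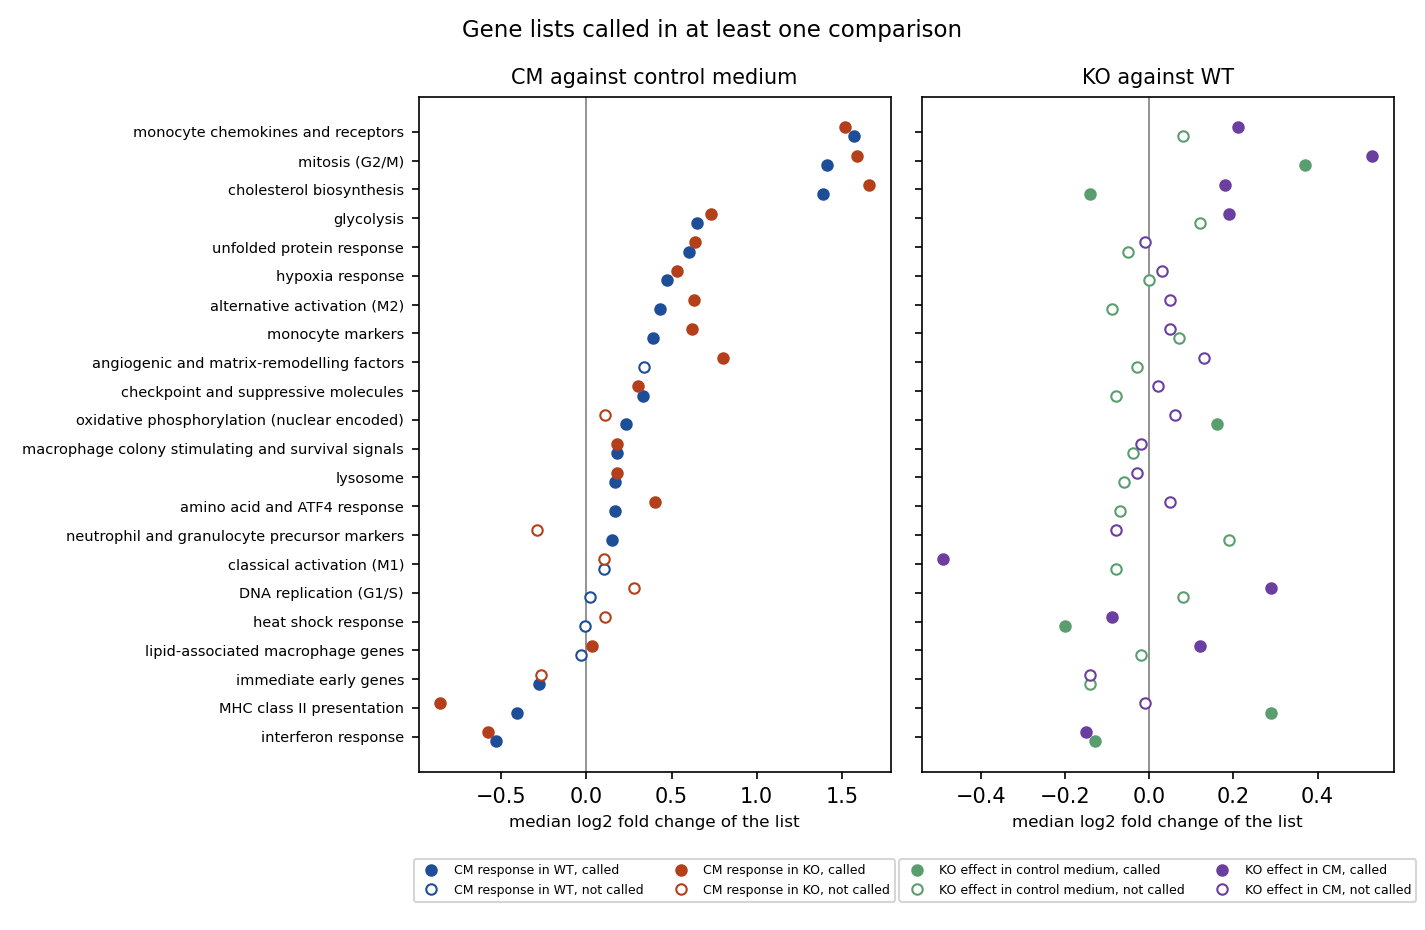
Median log2 fold change (x axis) of each gene list called in at least one of the comparisons shown (y axis), for CM against control medium (left) and KO against WT (right). Filled points passed camera at an adjusted p of 0.05 and open points did not; cholesterol synthesis has medians of 1.39 and 1.66 for CM in WT and KO.

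The next comparison asks how resting KO macrophages differ from WT macrophages. In control medium, KO cells had higher mitosis genes (16 of 36) and MHC class II genes (4 of 14) than WT cells, and slightly lower cholesterol synthesis genes (5 of 24). All 3 lists passed camera with the preset correlation, but each had adjusted p = 0.213 with an estimated correlation. The largest increase among genes admitted by the naming rule (mean of 4 CPM or more) was in Xlr, an X-linked lymphocyte-regulated gene, from 1.17 ± 0.37 CPM (n = 4) to 10.6 ± 1.38 CPM (n = 3; 3.14 ± 0.23, edgeR adjusted p = 3.21e-06). Lyz2, the lysozyme gene that carries the Cre, fell from 21890 ± 2358 to 10220 ± 155 CPM (-1.10 ± 0.07, edgeR adjusted p = 9.46e-07). The Cre is inserted in Lyz2, so this fall may come from the insertion and cannot be credited to the deletion in Ezh2. If the WT cells lack the Cre, other effects of the insertion cannot be told apart from those of the Ezh2 deletion either. In all, 708 genes passed, 375 higher and 333 lower, of which 78 and 19 differed by 2-fold or more.

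Beside Xlr, the admitted genes with the largest increases were Col4a6, a basement membrane collagen (1.81 ± 0.12), Pgm5 (1.56 ± 0.16), Hpgd (1.30 ± 0.15), the mitotic kinesin gene Kif18b (1.28 ± 0.20, not called from its most-counted exon, adjusted p = 0.154) and Eps8l1 (1.17 ± 0.12). Against WT libraries 1 and 2 alone they were 3.59 for Xlr, 1.83 for Col4a6, 1.66 for Pgm5, 1.19 for Hpgd, 1.06 for Kif18b and 1.10 for Eps8l1, and all passed. Below Lyz2, the largest decreases under that rule were in Slfn1 (-1.08 ± 0.27), Padi4, a peptidylarginine deiminase (-1.03 ± 0.09), the channel gene Mcoln3 (-1.01 ± 0.09), Klk1b11 (-0.77 ± 0.11) and Slfn3 (-0.76 ± 0.16). Within the batch these were -1.22 for Lyz2, -0.72 for Slfn1, -1.01 for Padi4, -0.96 for Mcoln3, -0.89 for Klk1b11 and -0.55 for Slfn3, all called. The calls of Slfn1 (adjusted p up to 0.122) and Slfn3 (up to 0.0893) were lost without WT control library 3 or KO control library 2 or 3, and that of Slfn1 also without WT control library 4 or KO control library 1. Xlr, Klk1b11, Slfn1 and Slfn3 belong to families of near-identical genes, so their reads may be split between copies and their values are uncertain.

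Mitosis genes were higher in KO in 16 of 36 cases with 0 lower (23 adjusted over the list alone, median 0.37, camera adjusted p = 2.07e-18, adjusted p = 0.213 with an estimated correlation). They include the spindle genes Cdc20 (1.04 ± 0.12) and Kif2c (1.01 ± 0.12) and the cyclin gene Ccnb2 (1.09 ± 0.15). Of 14 MHC class II genes 4 were higher and 1 lower (8 and 1 over the list alone, median 0.29, camera adjusted p = 0.000195, adjusted p = 0.213 with an estimated correlation). H2-Ab1 was higher by 0.66 ± 0.08 and H2-Eb1 by 0.52 ± 0.09. In cholesterol synthesis 5 of 24 were lower and 0 higher (the same over the list alone, median -0.14, camera adjusted p = 0.00799, adjusted p = 0.213 with an estimated correlation), such as Sqle (-0.59 ± 0.09). That list did not pass without WT control library 2 (0.0685). Oxidative phosphorylation had 3 of 41 higher (5 over the list alone, median 0.16, camera adjusted p = 0.000195, adjusted p = 0.464 with an estimated correlation). Heat shock genes had 1 of 16 lower (2 over the list alone, median -0.20, camera adjusted p = 0.00799, adjusted p = 0.513 with an estimated correlation). Within the batch the mitosis, MHC class II, cholesterol and oxidative phosphorylation lists passed (camera adjusted p = 5.03e-30, 2.42e-06, 4.54e-05 and 0.00273) and heat shock did not (0.171). The interferon list passed narrowly (1 of 44 higher, the same over the list alone, median -0.13, camera adjusted p = 0.0495, adjusted p = 0.714 with an estimated correlation; 6.61e-05 within the batch), and not without WT control library 1 or 2 (0.11 and 0.144), KO control library 3 (0.564), WT CM library 4 (0.0502) or KO CM library 2 (0.0571).

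The macrophage activation lists did not pass. In alternative activation 2 of 29 were higher and 3 lower (2 and 4 over the list alone, median -0.09, or -0.15 with the 3 genes absent from a group at their bounds, camera adjusted p = 0.39), with Clec10a at -0.35 ± 0.06 and Clec7a at 0.35 ± 0.06. Arg1 was near 0 in both genotypes (0.0362 ± 0.0464 and 0.115 ± 0.155 CPM; edgeR adjusted p = 0.343), and Mrc1 was 403.8 ± 59.4 and 420.1 ± 15.5 CPM (0.06 ± 0.10, edgeR adjusted p = 0.746), a difference of 0.25 with adjusted p = 0.031 against WT libraries 1 and 2 alone. Vegfa fell from 77.3 ± 7.45 to 53.9 ± 0.43 CPM (-0.52 ± 0.08, edgeR adjusted p = 0.00216; -0.39 within the batch, adjusted p = 0.000674). Cd274 (-0.16 ± 0.06, edgeR adjusted p = 0.11; -0.20 and 0.031 without WT control library 2), Tnf (-0.37 ± 0.16), Il1b (-0.34 ± 0.38), Il6 (0.91 ± 1.37), Il10 (-0.36 ± 0.20), Chil3 (0.09 ± 0.40) and Cd163 (0.02 ± 0.08) did not pass, and Retnla was at or under 3 counts in both genotypes. The M1 list had 1 of 23 lower (4 over the list alone, median -0.08, camera adjusted p = 0.075), and passed without WT control library 3 (0.0484) or KO control library 1 (0.0282). Typical developmental targets of PRC2 (1 of 12 lower, the same over the list alone, median -0.16, camera adjusted p = 0.535) did not pass. Nor did the other PRC2 subunits and H3K27 demethylases (0 of 16, 0 over the list alone, median -0.08, camera adjusted p = 0.297). Only expressed members of the developmental list were tested. Its other members had too few counts, and many had 0 in all 14 libraries, KO included. In the core macrophage list 3 of 24 were higher and 3 lower (4 and 3 over the list alone, median 0.02, mean -0.01, camera direction up, adjusted p = 0.924). The complement genes C1qa and C1qb were higher by 0.77 ± 0.09 and 0.53 ± 0.06.

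With WT libraries 1 and 2 alone, 514 genes passed, and of the 708, 344 (48.6%) were called again in the same direction. All 708 had the same sign, but they also had it with WT libraries 3 and 4 alone. The fits share libraries, so the sign tells little about the batch. The count rested on single libraries: it was 224, 282 and 244 without KO control library 2, 1 or 3, 285 and 330 without WT control library 3 or 4, and 1769 without WT control library 2. Scaling by library totals alone gave 605 higher and 182 lower genes.

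In CM, the comparison asks how KO macrophages differ from WT macrophages once exposed to hepatoma-conditioned medium. KO cells in CM had more Arg1 mRNA than WT cells, 191.3 ± 8.75 (n = 3) against 68.2 ± 9.48 CPM (n = 4; 1.49 ± 0.17, edgeR adjusted p = 0.000255). DNA replication (11 of 35) and mitosis genes (28 of 36) were higher in KO, but each list had adjusted p = 0.0517 with an estimated correlation. Lyz2, in which the Cre is inserted, was again lower, at 9478 ± 144 against 20460 ± 1188 CPM (-1.11 ± 0.07, edgeR adjusted p = 1.83e-06). In all, 611 genes passed, 413 higher and 198 lower, of which 46 and 21 differed by 2-fold or more.

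Xlr (2.91 ± 0.23), Pgm5 (2.00 ± 0.18), Col4a6 (1.46 ± 0.11) and Hpgd (1.13 ± 0.16) were again among the largest increases of genes admitted by the naming rule (mean of 4 CPM or more), with Uchl1, a deubiquitinase gene (1.09 ± 0.14). Within the batch the values were 2.85 for Xlr, 1.73 for Pgm5, 1.53 for Arg1, 1.40 for Col4a6, 1.07 for Hpgd and 0.94 for Uchl1, and all passed. DESeq2 did not call Arg1 (1.49, adjusted p = 0.159). The largest decreases under that rule were in H2-Q8 (-1.93 ± 0.40) and H2-Q6 (-1.66 ± 0.34), MHC class I genes that are near copies of each other and therefore uncertain, thrombospondin Thbs1 (-1.25 ± 0.22), Lyz2, the Notch ligand gene Jag2 (-0.85 ± 0.19) and the histone gene H2bc21 (-0.82 ± 0.12). Without KO CM library 1 or 2 the calls of H2-Q8 (adjusted p = 0.0661 and 0.0642), H2-Q6 (0.0681 and 0.0627) and Jag2 (0.0807 and 0.0705) were lost. All of these decreases passed within the batch (-1.77 for H2-Q8, -1.45 for H2-Q6, -1.14 for Thbs1, -1.08 for Lyz2, -1.04 for Jag2 and -0.67 for H2bc21).

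Mitosis genes were higher in 28 of 36 cases with 0 lower (35 adjusted over the list alone, median 0.53, camera adjusted p = 2.18e-32, adjusted p = 0.0517 with an estimated correlation). They include Cdc20 (0.68 ± 0.11) and Anln (0.55 ± 0.09). Of 35 DNA replication genes 11 were higher and 0 lower (20 and 1 over the list alone, median 0.29, camera adjusted p = 2.59e-11, adjusted p = 0.0517 with an estimated correlation), such as Rrm1 (0.49 ± 0.07) and Cdc45 (1.04 ± 0.17). Monocyte chemokines and receptors had 5 of 18 higher and 0 lower (8 and 1 over the list alone, median 0.21, camera adjusted p = 0.00543, adjusted p = 0.0517 with an estimated correlation). Cxcl14 was higher by 0.58 ± 0.11 and Pf4, platelet factor 4, by 0.70 ± 0.15. Both calls were lost without KO CM library 3 (0.0559 and 0.121). Glycolysis had 7 of 23 higher and 0 lower (10 and 1 over the list alone, median 0.19, camera adjusted p = 0.00148, adjusted p = 0.32 with an estimated correlation), led by Ldhb (0.89 ± 0.18). Cholesterol synthesis had 3 of 24 higher and 0 lower (8 and 1 over the list alone, median 0.18, camera adjusted p = 0.00538, adjusted p = 0.11 with an estimated correlation), with its regulator Srebf2 (0.30 ± 0.06) the smallest in p. Lipid-associated macrophage genes had 4 of 24 higher and 0 lower (the same over the list alone, median 0.12, camera adjusted p = 0.019, adjusted p = 0.29 with an estimated correlation). They include lipoprotein lipase Lpl (0.59 ± 0.07) and the scavenger receptor Cd36 (0.63 ± 0.10). Within the batch these lists passed, in the order given, with camera adjusted p = 3.14e-34, 9.07e-12, 2.55e-05, 1.09e-05, 0.000117 and 0.0211.

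In alternative activation only 2 of 29 genes were higher and 2 lower (3 and 2 over the list alone, median 0.05, mean -0.03, camera direction up, adjusted p = 0.227; 0.0801 within the batch): Arg1 and Clec7a (0.49 ± 0.06) higher, Tgm2 (-0.65 ± 0.09) and Cd209a lower. Cd209a (-1.72 ± 0.47, edgeR adjusted p = 0.0479) has near copies, is uncertain, and lost its call without any 1 of 10 libraries (adjusted p = 0.0603 to 0.143), the exceptions being the WT control libraries. Mrc1 was 846.4 ± 79.7 in WT and 989.8 ± 60.3 CPM in KO (0.23 ± 0.10, edgeR adjusted p = 0.187), and passed within the batch (0.28, adjusted p = 0.0185). The M1 list was lower (2 of 23 lower, 5 over the list alone, median -0.49, camera adjusted p = 0.019, adjusted p = 0.383 with an estimated correlation), but not within the batch (0.469) or without WT CM library 4 (0.0973) or KO CM library 2 (0.0729). Cd274 was higher (0.26 ± 0.06, edgeR adjusted p = 0.016; 0.26 and 0.0376 within the batch), a call lost without KO CM library 3 (0.078). Vegfa was lower (-0.37 ± 0.08, edgeR adjusted p = 0.0166; -0.25 and 0.016 within the batch), a call lost without WT CM library 4 or KO CM library 2 or 3 (0.0526, 0.055 and 0.0949). Il1b (-1.30 ± 0.40, edgeR adjusted p = 0.0792), Tnf (-0.33 ± 0.18), Il6 (-0.57 ± 0.75), Il10 (-0.04 ± 0.20), Retnla (0.64 ± 0.44), Chil3 (-0.45 ± 0.43) and Cd163 (0.00 ± 0.08) did not pass.

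The remaining lists in this comparison gave weaker results. The interferon (0 of 44 called, 0 over the list alone, median -0.15, camera adjusted p = 0.0103) and heat shock lists (0 of 16 called, 2 lower over the list alone, median -0.09, camera adjusted p = 0.0446) passed, with adjusted p = 0.715 and 0.586 with an estimated correlation and 0.256 and 0.648 within the batch. Interferon did not pass without WT CM library 3 (0.419) or KO CM library 2 (0.0562) or 3 (0.17), nor heat shock without WT CM library 3 (0.178) or 4 (0.0902) or KO CM library 2 (0.0626) or 3 (0.134). Angiogenic and matrix-remodelling factors had 6 of 30 higher and 2 lower (10 and 3 over the list alone, median 0.13, mean -0.03, camera direction up, adjusted p = 0.0515), with the collagenases Mmp8 at 0.94 ± 0.09 and Mmp13 at 0.76 ± 0.09. That list passed without WT control library 1, 2 or 3 (0.0433, 0.0477 and 0.0483), WT CM library 4 (0.0359), KO control library 2 (0.0493) or KO CM library 1 (0.0256). Checkpoint molecules (2 of 22 higher, the same over the list alone, median 0.02, camera adjusted p = 0.232) and developmental targets of PRC2 (0 of 12 called, 1 lower over the list alone, median -0.09, camera adjusted p = 0.47) did not pass.

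With WT libraries 1 and 2 alone, 478 genes passed, and 330 (54%) of the 611 were called again in the same direction. All 611 had the same sign, as they also had with WT libraries 3 and 4 alone, so here too the sign tells little. The count fell to 217, 307 and 363 without KO CM library 3, 1 or 2, and to 292 and 259 without WT CM library 3 or 4.

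The KO effects in the 2 media overlapped. Of the called genes, 159 were higher and 43 lower in KO in both media, against 11.6 and 4.95 for independent lists, and 0 were called in opposite directions (9 with the batch term). With WT libraries 1 and 2 alone 121 and 31 were shared (7.69 and 2.13 for independent lists). The lists are not independent, since WT control and CM libraries of the same number deviate together (r 0.33 to 0.47). Part of the overlap may therefore come from the WT libraries. Across genes the log2 fold changes correlated with r = 0.545, and with r = 0.213 within the batch.

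Whether KO cells respond to CM differently from WT cells was tested as a genotype by medium interaction. The response of the cholesterol synthesis list was larger in KO, also with an estimated correlation (camera adjusted p = 0.00194). That of MHC class II genes was more negative, but had adjusted p = 0.0684 with an estimated correlation. The median MHC class II difference of KO from WT was 0.29 in control medium and -0.01 in CM. By these medians the KO level was higher than WT before CM and near WT in CM, not below it. For cholesterol synthesis the medians of KO against WT were -0.14 in control medium and 0.18 in CM. At single genes 0 of 13311 passed edgeR's test, with 1050 at an unadjusted p under 0.05 where 666 are expected; DESeq2 called 71 and limma-voom 27. With WT libraries 1 and 2 alone edgeR called 11, with libraries 3 and 4 alone 54, and with the library batch as a term 164; without WT control library 2 it called 2, and without KO CM library 2 it called 1.

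Cholesterol synthesis genes had a median interaction of 0.24 (10 of 24 higher and 0 lower adjusted over the list alone, camera adjusted p = 4.54e-12, 0.00194 with an estimated correlation, 4.6e-14 within the batch). Sqle had 0.54 ± 0.13. DNA replication genes had a median of 0.25 (8 higher over the list alone, camera adjusted p = 1.91e-08, adjusted p = 0.0684 with an estimated correlation; 4.09e-06 within the batch), with Rrm1 at 0.38 ± 0.10. The MHC class II median was -0.27 (4 lower over the list alone, camera adjusted p = 1.11e-06, adjusted p = 0.0684 with an estimated correlation; 4.09e-06 within the batch). H2-Ab1 had -0.60 ± 0.12 and H2-Eb1 -0.65 ± 0.13. Oxidative phosphorylation (median -0.12; 0 of 41 over the list alone, camera adjusted p = 9.24e-05, adjusted p = 0.382 with an estimated correlation) and lipid-associated macrophage genes (median 0.10; 2 of 24 higher over the list alone, camera adjusted p = 0.00626, adjusted p = 0.154 with an estimated correlation) also passed. So did the ATF4 list (median 0.09; 2 of 31 higher over the list alone, camera adjusted p = 0.033, adjusted p = 0.0878 with an estimated correlation), but not within the batch (0.0513) or without WT control library 4 (0.13) or WT CM library 1 (0.074) or 2 (0.0973).

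Alternative activation did not pass (1 of 29 higher over the list alone, median 0.12, camera adjusted p = 0.0867), but did without WT control library 1 (0.0322) or 2 (0.0472) or KO CM library 1 (0.0482) or 2 (0.0497). By the rule for naming, the single genes nearest to passing were Igf2bp2 (0.66 ± 0.10, edgeR adjusted p = 0.11), Anxa3 (0.37 ± 0.07, 0.148) and Clec10a (0.43 ± 0.08, 0.148) above 0, and Agbl5 (-0.91 ± 0.15, 0.11), Ufc1 (-0.38 ± 0.07, 0.148) and Tomm7 (-0.86 ± 0.16, 0.148) below 0. Igf2bp2 passed without WT control library 2 (0.72, adjusted p = 0.02) and Agbl5 without KO CM library 2 (-1.10, 0.000449). With the library batch as a term all 6 passed (edgeR adjusted p = 0.00111 for Igf2bp2, 0.00148 for Anxa3, 0.00465 for Clec10a, 0.00229 for Agbl5, 0.00465 for Ufc1 and 0.00516 for Tomm7). Within WT libraries 1 and 2 Igf2bp2 (0.56, 0.0363) and Anxa3 (0.41, 0.0418) passed and the other 4 did not. Of the fixed genes, Cd274 had 0.42 ± 0.08 (edgeR adjusted p = 0.148; 0.00631 with the batch term and 0.163 within WT libraries 1 and 2), Mrc1 0.17 ± 0.14, Vegfa 0.15 ± 0.11, and Arg1 0.11 ± 1.54 (edgeR adjusted p = 0.998), the last resting on 12 counts in WT control medium.

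Finally, the KO effect in CM was set against the CM response itself across genes, to ask whether KO cells in CM lie further along that response. With the CM response in WT, which uses the same WT CM libraries, r was 0.008, against -0.465 in simulated noise. The simulated data held neither a KO effect nor a CM response, so their r is on another scale. Only the covariances can be compared (0.00178 against a simulated -0.0226). When the WT CM libraries were split so that no library served both sides, r was 0.056 to 0.083, and with WT libraries 1 and 2 alone it was -0.083. The simulated libraries were independent, while the real WT control and CM libraries deviate together, which makes r less negative without any KO effect. Each split also mixed the batches, so these values do not decide the question. With the CM response in KO, which shares the KO CM libraries, the covariance was 0.0653 against a simulated 0.0297. The r of 0.256 cannot be compared with the simulated 0.531, for the same reason of scale.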

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

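The tests of the library batch against the KO calls, of genes linked to the engineered loci, of loss of Ezh2 at weakly expressed genes, and of the batch in the interaction were chosen only after the results were seen.

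The response to CM differed between genotypes in 6 gene lists by the interaction test: cholesterol synthesis (camera adjusted p = 4.54e-12), DNA replication (1.91e-08), MHC class II (1.11e-06), oxidative phosphorylation (9.24e-05), lipid-associated macrophage genes (0.00626) and the ATF4 list (0.033). With an estimated correlation only cholesterol synthesis passed (0.00194), and the other 5, in the order given, had adjusted p = 0.0684, 0.0684, 0.382, 0.154 and 0.0878. The ATF4 list also did not pass within the batch (0.0513). Ufc1 in WT control library 2 lay far from the other 3 libraries of its group (84.3 CPM against 79.7 to 79.9). It was 1 of 99 groups of 4 looked at, where chance gives about 5.

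KO and WT cells differed in 708 genes in control medium and 611 in CM. WT libraries 1 and 2 group with the KO in exon shares and coverage. Against those alone, the median ratio of the log2 fold change to the pooled one was 0.86 in control medium and 0.89 in CM. The genes were selected in a fit that shares the KO libraries and WT libraries 1 and 2, which itself keeps the ratio near 1. The ratio therefore does not decide how far the batch of WT libraries 3 and 4 contributes. Without WT libraries 3 and 4, 344 of the 708 and 330 of the 611 were called again. A further technical difference between WT libraries 1 and 2 and the KO stays open, as they lie apart on the third principal component (-25.6 to -11.5 against 4.9 to 13.9). Tested genes near the engineered Ezh2 and Lyz2 loci were too few to make up most of the calls in any case, so only their share can be compared. Of 174 tested genes within 10 Mb, 8 were called in control medium (4.6% against 5.3% of all genes, Fisher exact p = 0.864). In CM 13 of 174 were called (7.5% against 4.6%, Fisher exact p = 0.0961), so an excess there was neither shown nor excluded. Of 35 splits of the libraries, 2 called as many genes as the real one in control medium (the other called 1606, with WT control library 2 joined to KO), so a split by chance is not excluded there, while in CM the real split was the 1 with as many (the next called 81). For CM in WT 1 of 35 splits called as many (the next, 2549, was the batch itself), and for CM in KO 1 of 10, too few splits to decide. Which animals the libraries came from stays open.

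The interaction called 0 genes by edgeR, with 1050 at an unadjusted p under 0.05, 71 called by DESeq2 and 27 by limma-voom. All 100 drawn regroupings of genotype called 0 or more (up to 1292), as they had to, so that count decides nothing about chance. With the library batch as a term 164 genes passed, so the batch may have hidden differences, and 2 of 100 regroupings outside that batch called as many (up to 166). The single genes that the batch term adds are therefore a hypothesis found on the same data.

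Weakly expressed called genes, under 1 CPM, were mostly higher in KO. In control medium 35 of 38 were (92.1%) against 340 of 670 others (50.7%, Fisher exact p = 1.33e-07). In CM 23 of 32 were (71.9%) against 390 of 579 others (67.4%, Fisher exact p = 0.7), so no excess was shown there. The CM responses had 324 of 773 higher (41.9%), a difference of 50.2 percentage points in control medium and 30 points in CM (Fisher exact p = 3.84e-10 and 0.000921). The 773 calls pool both genotypes, so a gene called in both counts in each, and these p-values treat such calls as independent. The difference does not decide on a counting floor at low expression. Each CM comparison sets libraries over similar ranges of depth against each other, while the deepest WT libraries were deeper than any KO library. Against WT libraries 1 and 2 alone the excess in control medium was 9.8 points (12 of 18 against 282 of 496, Fisher exact p = 0.474). In CM it was -3.8 points (9 of 13 against 338 of 463, Fisher exact p = 0.756). The library batch may thus account for the excess in control medium, on few genes. Loss of Ezh2, which could leave silent genes higher, is neither shown nor excluded by the same 9.8 and -3.8 points, on 18 and 13 genes.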

How the results depend on the processing

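Fits with the library batch as a term, with WT libraries 1 and 2 or 3 and 4 alone, with all exon entries and with the most-counted exon were chosen after the data were seen. Across 340 values of named genes, DESeq2 size factors changed 0 calls and dropping the filter 2. The stricter filter tested 328 of them and changed 1. The most-counted exon lost 24 calls, gained 1 and reversed 3, the fit of only the compared groups (288 values) lost 17 and gained 6, DESeq2 gained 31, lost 1 and reversed 1, limma-voom gained 35, lost 1 and reversed 2, WT libraries 3 and 4 alone gained 46, lost 1 and reversed 5, and 304 kept direction and call with WT libraries 1 and 2 alone (15 lost, 14 gained, 7 reversed). Of 63 list results 30 lost their call with an estimated correlation, and 33 stayed as they were (19 called, 14 not called). The cause was not tested for the changes below, except that a stricter threshold leaves fewer calls. At 1.5-fold the interaction recovered 40.3% of simulated changes. The fit of only the compared groups was not run for the interaction, which needs all 4.

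CM calls kept within 1.5 times under all alternatives except a 2-fold minimum (1003 in WT, 1187 in KO). KO calls in control medium (708) were 1470 with DESeq2, 4757 with limma-voom, 283 with only the compared groups, 384 with the most-counted exon, 5246 with WT 3 and 4 alone, 174 at 0.01, 97 at 2-fold, and 224 to 1769 leaving out a library. KO calls in CM (611) were 1184 with DESeq2, 1794 with limma-voom, 923 with the batch term, 4791 with WT 3 and 4 alone, 173 at 0.01, 67 at 2-fold, and 217 to 721 leaving out a library. Interaction calls (0) were 71 with DESeq2, 27 with limma-voom, 164 with the batch term, 11 with WT 1 and 2 alone, 54 with WT 3 and 4 alone, and 0 to 2 leaving out a library. Genes higher in KO in both media (159) were 268 with DESeq2, 96 with the most-counted exon, 1643 with WT 3 and 4 alone, 53 at 0.01 and 84 to 204 leaving out a library. Those lower (43) were 137, 27, 1708, 13 and 20 to 88, and 83 with the batch term. The r of the KO effect in CM with the CM response in WT was -0.083 with WT 1 and 2 alone.

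Ezh2 in control medium (-0.31) was called with DESeq2 (-0.31, adjusted p = 0.0326), limma-voom (-0.39, 0.00374) and WT 3 and 4 alone (-0.44, 0.00053), with -0.37 to -0.24 leaving out a library. In CM it was -0.34 with WT 1 and 2 alone, not called, and -0.45 to -0.33 leaving out a library. Lists called with an estimated correlation were 9 for CM in WT, 10 for CM in KO, 0 for KO in either medium and 1 for the interaction. With fry 27 were called for CM in WT and 10 for KO in control medium, with the most-counted exon 10 for KO in control medium, and with WT 3 and 4 alone 14 for the interaction.

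Directions reversed as follows, none a call except Aldoa and the interferon list. CM in WT: Chil3 0.05 (limma-voom) and 0.11 (WT 3 and 4), Il1b -0.06 (most-counted exon) and -0.14 (WT 1 and 2), Lyz2 0.07 (WT 3 and 4). KO in control medium: Arg1 -0.58 (most-counted exon), Cd163 -0.04 (batch term) and -0.06 (WT 1 and 2), Chil3 -0.01 and -0.13 (the same), Mrc1 -0.05 (limma-voom) and -0.11 (WT 3 and 4). KO in CM: Aldoa 0 (most-counted exon, from 0.21), Cd163 0.02 (library totals) and 0.05 (WT 3 and 4), Il10 0.13 (batch term) and 0.3 (WT 1 and 2). Interaction: Arg1 -0.02 (DESeq2) and -4.06 (WT 1 and 2, a fitted value with 0 counts in WT control medium), Cd163 0.01 and Lyz2 0.14 (WT 1 and 2), Ezh2 0.01 (WT 3 and 4). Lists, as camera adjusted p: alternative activation in KO in control medium 0.803 (WT 1 and 2), developmental targets 0.988 (most-counted exon), 0.616 (batch term) and 0.628 (WT 1 and 2) in control medium, and 0.73 and 0.829 (batch term, WT 1 and 2) in CM, interferon in CM 0.256 (WT 1 and 2), core macrophage genes 0.871 (no filter) and 0.932 (most-counted exon) for CM in WT and 0.478 (WT 3 and 4) for KO in control medium.

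Leaving out a library also turned Chil3 (-0.37 to 0.22) and Il1b (-0.37 to 0.4) for CM in WT and Il10 for CM in KO (-0.27 to 0.12). For KO in control medium it turned Arg1 (-0.58 to 2.35), Cd163 (-0.01 to 0.06), Chil3 (-0.13 to 0.46), Il6 (-3.53 to 1.79), Mrc1 (-0.01 to 0.12) and Retnla (0 to 3.92), and in CM Cd163 (-0.08 to 0.07) and Il10 (-0.23 to 0.17). For the interaction it turned Arg1 (-0.86 to 2.07), Cd163 (-0.1 to 0.05), Il6 (-2.35 to 2.96), Lyz2 (-0.06 to 0.05), Retnla (-3.29 to 0.64) and Tnf (-0.11 to 0.2). The core macrophage list turned for CM in WT (adjusted p 0.787 to 0.969) and KO in control medium (0.699 to 0.993).

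With the replicate block, calls were 5449 for CM in WT, where the numbers pair the libraries by the preset rule, and it changed no other call there than the M1 and neutrophil lists. KO libraries of the same number did not deviate together (-0.04 to 0.05, only number 3 best with its own), and of WT and KO libraries only number 2 in control medium did (0.12), not every pair. There the block gave 5591 calls for CM in KO, 826 and 581 for KO in control medium and CM, 0 for the interaction, and turned Il10 (0) and Il6 (0.04) in CM. Over all comparisons the block lost 5 and gained 3 calls among 340 values of named genes. Among 63 list results it lost 4 and gained 2.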

Other observations

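The values below are of tests and selections chosen after the results were seen.

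KO cells differed from WT cells in 107 genes in both media under each of 3 fits, with all libraries, with the batch term and with WT libraries 1 and 2 alone, 86 higher and 21 lower. Beside Xlr, Pgm5, Col4a6, Hpgd and Eps8l1, the largest mean increases among those with a mean of 4 CPM or more included Cdc42bpa, a kinase (1.01 in control medium and 1.05 in CM), Ube2c, a ubiquitin-conjugating enzyme of mitosis (1.08 and 0.89), and Depdc1a (1.13 and 0.82). Below 4 CPM, mean increases above that of Xlr were those of Loxl2 (5.13 and 5.28) and Atp9a (3.46 and 2.87), at 0.326 and 0.591 CPM. Epn2, at 1.58 CPM, was lower (-1.27 and -1.74). Beside Lyz2, which carries the Cre, the decreases included Padi4 (-1.03 and -0.76), Mcoln3 (-1.01 and -0.80), Wwc2 (-0.72 and -0.77), the macrophage growth factor gene Csf1 (-0.75 and -0.58), Tgm2 (-0.39 and -0.65) and the receptor gene Fgfr1 (-0.56 and -0.40). The 3 fits share the KO libraries and WT libraries 1 and 2, so passing all of them is not repeated support. The media are not independent either, since WT libraries of the same number deviate together.

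Called genes with opposite CM responses in the 2 genotypes numbered 4 (20 with the batch term): Agbl5 (0.31 in WT, -0.60 in KO), Cpt1b (0.61 and -0.83), Tomm7 (0.29 and -0.57) and Ufc1 (0.16 and -0.23). None of these 4 passed the interaction test without the batch term. Cpt1b lay at the threshold in WT (edgeR adjusted p = 0.05). Of 22 hepatocyte and hepatoma markers 4 were tested: Ambp rose with CM (3.43 in WT and 2.85 in KO), Trf fell (-0.72 and -0.96), and Afp (0.37 and -0.23) and Apoa2 (0.18 and -0.14) were not called.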
